A study of Mus musculus with 3 samples.

How the data were processed

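Droplet single-cell RNA sequencing measured gene expression in stromal vascular cells of the mesenteric fat of 3 perfused C57BL/6 mice: 1 control, 1 with a primary and 1 with a secondary infection by *Heligmosomoides polygyrus*. Per the labels' protocols, the fat was minced, digested with Liberase and DNase I, filtered and spun to separate stromal vascular cells from adipocytes, and libraries were made with Chromium 3' chemistry. No sort or gate is described. The authors deposited, for each library, whole-number counts of unique molecules (UMIs) per gene and cell barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 2.2, Seurat 3 and the mm10 genome build were used. The annotation release, the alignment settings and any removal of cells before deposit are not given in the sources used here. The smallest barcode of the control, primary and secondary library holds 1031, 943 and 999 UMIs, so empty droplets had been left out before deposit.

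Each library has 27998 gene rows. The 121 rows that shared a symbol with another were summed by symbol, which left 27933 genes. Ensembl gene IDs and symbols are those of the deposited gene tables, and positions are from a GENCODE annotation of GRCm38, where all 378 genes named or held in a list were matched by ID. Barcodes with fewer than 200 genes (0, 7 and 0 in control, primary and secondary) or with over 10% mitochondrial UMIs (2, 5 and 1) were removed. Doublets were scored in each library with Scrublet's method, rewritten with exact neighbours and 2 simulated doublets per cell. The highest scores were removed up to an expected rate of 0.8% per 1000 barcodes, which took 166, 171 and 28 barcodes. The kept cells numbered 4394, 4440 and 1847, with medians of 2669, 2831 and 2974 UMIs.

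The 3 libraries were clustered together without integration: UMIs per 10000, log scale, 2000 variable genes, 30 principal components, 20 nearest neighbours, a graph of shared neighbours and Leiden clustering at resolution 1. An annotation of cells by the authors was not used here, so clusters were named from marker lists fixed before the data were examined. A marker counted where at least 10% of a cluster's cells had a UMI and its level was at least 2 times the median over clusters. A name needed 3 such markers. The scoring was set after the clusters had been seen. In particular, a cluster stayed unnamed when an immune and a non-immune class each had at least 40% of their markers in it, at 0.2 or more of the highest cluster's level; the threshold had first been set higher. This keeps out cluster 15, which has markers of fibroblasts and of type 2 innate lymphoid cells (ILC2) and holds 1.59, 1.13 and 2.22% of the control, primary and secondary cells. Macrophage cluster 6 has 9 of the macrophage markers, none among its 10 leading genes, and also 5 monocyte markers, so the macrophage class includes cells close to monocytes. Dendritic cell cluster 17 has 4 of 13 dendritic cell markers and 4 of 11 monocyte markers, so its name is less certain. T cell cluster 8 has 7 of 9 T cell markers and 8 of 11 ILC2 markers, with 3 of each among its 10 leading genes. Its name was therefore a close call between these classes. The T cell, fibroblast and macrophage classes were clustered again at resolution 0.6. The resulting macrophage subcluster 2 has fibroblast-type genes among its leading genes (Serpinh1, Mgp, Sparc, Dcn), a median of 5071 UMIs, and 17.1, 23.7 and 12.0% of the control, primary and secondary class.

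With 1 mouse per group, no test, p-value or standard error was computed, and no count of changed genes was made from cells. UMIs were summed per class and library and expressed as CPM, a gene's UMIs over all UMIs of the class. Ratios of 2 libraries have exact conditional binomial 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. Both cover counting error only, and the gene ratio intervals take each UMI as an independent draw, without differences between cells of a class. Against a count of 0, a floor of 3 UMIs in that class and library gives a lower bound of the ratio. For each of the 33 gene lists, log2 ratios (prior of 1 UMI) of the members with at least 10 UMIs over the 2 libraries gave a median. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries only. A list with at least 4 measured members is said to stand apart at or under percentile 2.5 or at or over percentile 97.5. Members at least 1.5-fold higher or lower were counted. Shares of cells with a UMI are given with all UMIs and after thinning each cell to 1000 UMIs, with the share in a class that should lack the gene as background.

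Genes to name were chosen by a rule fixed before the data were examined, as were the lists, the comparisons and all but 3 of the alternatives. In the 4 classes with the highest mean share among named classes with at least 50 cells in every library (fibroblast, macrophage, T cell and dendritic cell), genes were ranked by the bound of the ratio's interval nearest to 1. The 4 highest and 3 lowest were taken for each infection against control, and the 2 highest and 2 lowest for secondary against primary. In the library where it was higher, a gene needed 20 UMIs, 50 CPM, 10 cells with a UMI, a level of at least 0.2 of the highest class, and a ratio of at least 1.5. Mitochondrial and ribosomal protein genes, Malat1, Xist, Y-linked genes, antigen receptor segments and the lists of dissociation, cell cycle and other-tissue RNA were not ranked. Of each list, members with the 4 highest levels served as examples, and any other gene named is marked as chosen after its values were seen.

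Alternatives varied the filters on cells, the removal of doublets, the clustering resolution, the neighbours, the depth, the normalization, the weight of cells, the filter on low counts and the prior. The other 3 alternatives were added after the data had been seen. Median-of-ratios scaling moved ratios by at most 0.07 on the log2 scale in any of the 4 classes. Ratios, intervals and list percentiles were tested on simulated counts with 200 of 2200 genes changed. Each gene's total was drawn as a Poisson count, without cells. The coverage therefore checks the computation, and not the intervals of genes whose UMIs are held by few cells. For primary over control, secondary over control and secondary over primary, 95.6, 96.7 and 97.1% of true ratios lay inside their intervals. Of the genes changed 2-fold, 86, 88 and 76% met the size rule, as did 2.75, 2.85 and 2.00% of unchanged genes. The programs were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Immunoglobulin heavy chain genes are absent from the deposited gene tables and were not analysed here, and the gene rule took neither NK cells, which rank below the 4 classes in mean share, nor the classes with fewer than 50 cells in a library (B, ILC2, plasma, endothelial and mesothelial cells).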

Results

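The mesenteric fat lies between the intestine and the lymph nodes that drain it. The 3 libraries address how infection of the gut by the roundworm *Heligmosomoides polygyrus*, a strong inducer of type 2 immunity, is reflected in the stromal and immune cells of this fat, and what a second infection adds after the first has been cleared. Stromal vascular cells of 1 mouse per group were profiled: a control given no larvae, a primary infection (1 gavage of 200 larvae) and a secondary infection (2 gavages, with 1 mg of pyrantel, a drug that expels the worms, and 4 to 5 weeks of recovery between them). Tissue was taken 11 to 13 days after the last gavage. The control, primary and secondary libraries held 14153269, 14723429 and 6420029 unique molecules (UMIs) in 4562, 4623 and 1876 barcodes, with medians of 2721, 2883 and 3009 UMIs per barcode. After filters and removal of the highest doublet scores, 4394, 4440 and 1847 cells remained. With 1 mouse per group no difference has a replicate check and none was tested. All intervals are 95% intervals that cover counting error only, not differences between mice, digestions or libraries. Those of gene levels and ratios take each UMI as an independent draw, without differences between cells of a class. They are too narrow where few cells hold most of a gene's UMIs.

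Clustering gave 10 named classes and a class of cycling cells, each called by the type whose markers it carries. Fibroblast-like cells made up 54.3, 58.5 and 51.4% of the control, primary and secondary cells, and immune classes together 39.5, 36.2 and 41.3%. Macrophage-like cells were the main immune class in the control, at 58.2% of immune cells, against 31.5% in the primary and 13.1% in the secondary library. T cell-like cells were 15.7, 28.7 and 49.8% of immune cells in the same order. ILC2-like cells, innate producers of type 2 cytokines, were 2.59, 2.73 and 2.17% of all cells, and dendritic cell-like cells 3.25, 2.77 and 3.47%. How well each type is released by the digestion affects all of these shares. An unnamed cluster with fibroblast and ILC2 markers held a further 70, 50 and 41 droplets, and the 40% threshold that keeps it out was set after the clusters had been seen.

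**Figure D1:**
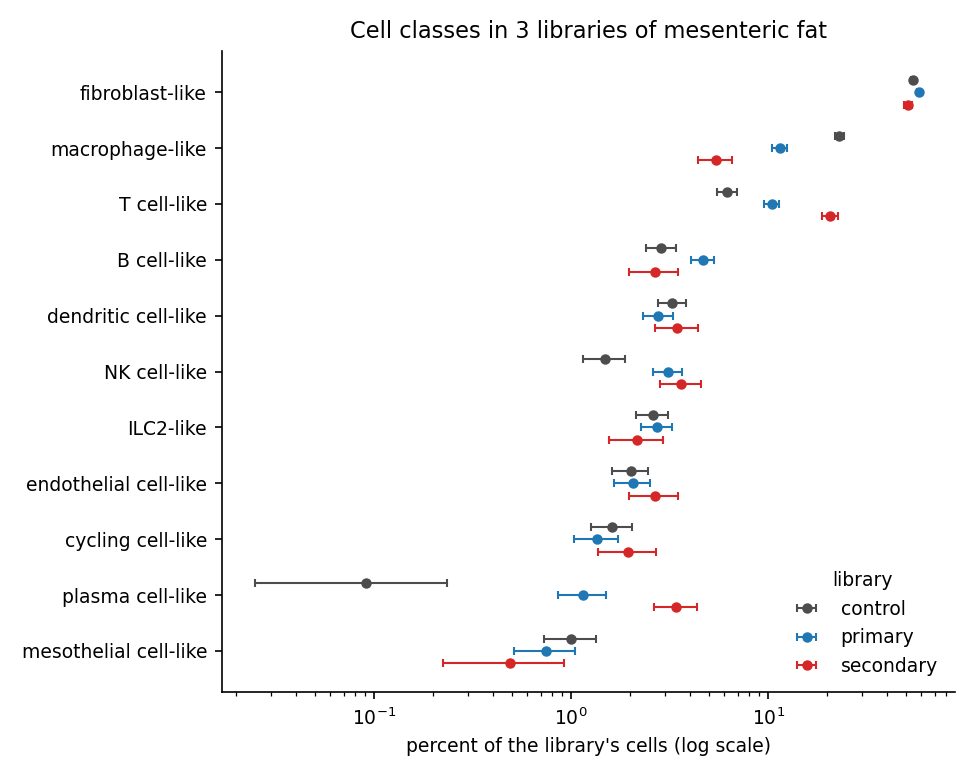
Share of each cell class in the control, primary and secondary libraries (percent of the library's cells, log scale), with exact Clopper-Pearson 95% intervals; 1 mouse per group. Macrophage-like cells go from 23% in the control to 5.41% in the secondary library, while T cell-like cells go from 6.21 to 20.6% and plasma cell-like cells from 0.0910 to 3.41%.

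The comparison of primary infection with control asks what a first encounter with the worm leaves in the fat. T cell-like cells were 1.67-fold (1.44 to 1.95) more frequent among all cells after primary infection, NK cell-like cells 2.09-fold (1.54 to 2.85) and B cell-like cells 1.63-fold (1.30 to 2.05). Plasma cell-like cells, the antibody secretors, were 12.6-fold (4.64 to 48.1) more frequent, from 4 to 51 cells. Macrophage-like cells were 2.01-fold (1.81 to 2.24) less frequent. The shares of ILC2-like, dendritic cell-like and endothelial cell-like cells had ratios of 1.05 (0.807 to 1.37), 0.851 (0.663 to 1.09) and 1.02 (0.755 to 1.39), differences not detectable at this depth.

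Within T cell-like cells, genes of the type 2 program were higher after primary infection. Of 13 measured type 2 cytokine and receptor genes, 12 were at least 1.5-fold higher. They included Plac8 at 12.0-fold (8.66 to 17), Areg, an epithelial growth factor, at 9.51-fold (5.85 to 16.5), Gata3, the master regulator of type 2 T cells, at 5.02-fold (3.69 to 6.98), and Il1rl1, the receptor for interleukin 33, at 3.99-fold (2.37 to 7.19). The exception was Ccr4, with a ratio of 0.633 (0.289 to 1.42), singled out after its values were seen. The list's median log2 ratio was 2.64, or 2.37 with the 3 members without control UMIs at their bound, at percentile 100 of the random lists. Il13, which drives mucus and smooth muscle responses to worms (ENSMUSG00000020383; chromosome 11, 53631324 to 53634702, GRCm38), had 0 UMIs in the control and 69 in the primary library, at least 11.1-fold higher (44.9% in 5 cells). Ccl1, the chemokine ligand of Ccr8, was 140-fold (24.9 to 5543) higher from 1 control UMI, Hdc, the enzyme that makes histamine, 47.2-fold (12.9 to 392) from 2, and the galectin gene Lgals7 42.6-fold (14.4 to 208) from 3. Regulatory T cell genes also stood apart, with a median of 0.45 (percentile 99.3) and 3 of 9 members higher, led by Tnfrsf4 (OX40) at 3.41-fold (2.43 to 4.90), but the median was -0.30 among members with at least 50 UMIs. Tnfrsf4 is also a leading gene of cluster 8, as are Areg and Il1rl1, and Foxp3 UMIs were in 1.10% of control and 0.866% of primary cells.

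Type 17 and naive T cell genes were lower after primary infection. All 4 measured type 17 genes were at least 1.5-fold lower, with a median of -1.71 (percentile 0), and Tmem176b was 3.62-fold lower (2.84 to 4.62). Blk, a kinase used by interleukin 17-producing gamma-delta T cells, was 7.75-fold lower (3.47 to 19.6), and Ramp1, part of the receptor for the neuropeptide CGRP, 3.57-fold lower (2.65 to 4.83). Among naive and recirculating T cell genes, 8 of 12 were at least 1.5-fold lower (median -0.85, percentile 0), with the transcription factor genes Lef1 and Tcf7 at ratios of 0.464 and 0.522. Type 1 and cytotoxic genes did not stand apart (median -0.22, percentile 3.76), though they did with at least 500 genes per cell (-0.37), nor did residency genes (median 0.06), and only 3 of 9 follicular helper genes were measured, too few to call. Cells with a Gata3 UMI were 13.9% of the control and 40.3% of the primary class (9.89 and 27.0% after thinning to 1000 UMIs per cell, which left out 0 and 6 cells), against 0.126 and 0.269% of fibroblast-like cells. Median depths were 1585 and 1921.5 UMIs in T cell-like and 2857 and 3090 in fibroblast-like cells. Cluster 7 held most control T cell-like cells (183 of 273), and cluster 8, led by Areg, Cd3g and Tnfrsf4, the largest part of the primary ones (174 of 462, against 13 in the control). Weighting every cell alike moved the log2 ratio of Ccl1 from 6.41 to 5.78.

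In fibroblast-like cells, Mrgprg, an orphan receptor of the Mas-related family (ENSMUSG00000050276; chromosome 7, 143763710 to 143766993), had the highest rank, at 0.849 CPM in the control and 127 CPM after primary infection, 150-fold higher (68.6 to 409). Daglb, which makes the lipid mediator 2-arachidonoylglycerol, was 5.23-fold higher (4.54 to 6.05), Aif1l 5.61-fold (4.51 to 7.05) and Smpd3, a neutral sphingomyelinase, 4.42-fold (3.99 to 4.91). Mrgprg UMIs were in 9.74% of the primary cells, so the ratio of Mrgprg does not describe the whole class. Mrgprg, Daglb and Smpd3 are leading genes of fibroblast subcluster 3, which held 0 control and 182 primary cells. Their ratios are not separated from the appearance of this subcluster. Cyp26b1, which breaks down retinoic acid, was 5.78-fold lower (4.57 to 7.39), the estrogen sulfotransferase Sult1e1 3.31-fold lower (2.72 to 4.05) and the neuropeptide gene Nmb 2.30-fold lower (1.94 to 2.72). Fibroblast subcluster 1, with Pi16, Cd55 and Dact2 among its leading genes, made up 16.0% of the control and 30.3% of the primary class. Beside this change in composition, interstitial progenitor genes stood apart as higher (median 0.48, percentile 100, 5 of 12 at least 1.5-fold), with Pi16 at 1.99-fold (1.92 to 2.06). So did complement genes (median 0.28, percentile 99.9, 4 of 11), with C4b at 3.71-fold (3.30 to 4.18) and C3 at 1.67-fold (1.64 to 1.71). Fibrillar collagen and matrix genes had a small shift (median 0.19, percentile 100), with 2 of 29 at least 1.5-fold higher and none that much lower, and MHC class I genes a median of 0.30 (percentile 100), led by H2-K1 at 1.72-fold (1.62 to 1.83). MHC class II genes were lower, with a median of -0.67 (percentile 0.01) and Cd74 at a ratio of 0.589 (0.530 to 0.656). Fibroblast subcluster 6, led by myeloid genes, held 66 control and 17 primary cells, and without it that median was -0.60. Macrophage RNA in these droplets was lower alongside, with UMIs of Retnla in 27.3% of control and 20.1% of primary fibroblast-like cells (9.43 and 7.24% thinned, leaving out 0 and 16), so the class II difference is not separated from free RNA.

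Smaller shifts in the same cells were a median of -0.18 (percentile 1.53) for basement membrane genes and 0.15 (percentile 99.3) for adipogenic genes, 7 of 17 at least 1.5-fold higher, with Apoe, a lipid carrier, at 1.91-fold (1.79 to 2.03). The adipogenic list no longer stood apart with doublets kept (median 0.11). TGF-beta response genes (median -0.07) and stromal cytokine genes (median -0.08) did not stand apart. Cells with a UMI of Il33, an alarm cytokine that activates ILC2, were 13.5% of the control and 27.5% of the primary fibroblast-like cells (5.53 and 11.1% thinned, leaving out 0 and 16 cells), against 0 of 273 (a share with a UMI of up to 1.10% by the floor of 3) and 0.216% of T cell-like cells. Cluster 0, led by Dcn and Clec3b, held the largest part of the class in both libraries (1152 of 2387 and 886 of 2598), while cluster 4, led by Postn, Ccl11 and Smpd3, held 2 control and 356 primary cells.

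Macrophage-like cells carried fewer resident transcripts after primary infection. Of 15 perivascular resident genes, 12 were at least 1.5-fold lower (median -0.89, percentile 0). Among them were the platelet factor gene Pf4 at 4.68-fold lower (4.45 to 4.93), the folate receptor gene Folr2 at 3.18-fold lower (2.90 to 3.49; chromosome 7, 101839988 to 101857194) and the lectin gene Cd209f at 3.41-fold lower (2.97 to 3.93). The chemokine gene Ccl8, named after its values were seen, was 2.94-fold higher (2.59 to 3.33), and 2 members lay within 1.5-fold. Among cells with UMIs of at least 2 C1q genes, 88.9% of the control and 70.0% of the primary class, the median was -0.63 with 9 of 15 lower, and a subcluster with the monocyte genes Plac8 and Ly6c2 held 2.28 and 11.6% of the class. Ccl3, a chemokine for inflammatory cells, was 5.04-fold lower (4.26 to 6.02). Chil3 (Ym1), a chitinase-like mark of type 2 activation, was 182-fold higher (110 to 326; 14.0% of cells against 0.694% in the control, 9.46 and 0.297% thinned with 10 and 0 cells left out, and at most 1.00% of fibroblast-like cells) and the acute-phase gene Saa3 35.1-fold higher (30.4 to 40.9). Chil3 is also on the list of monocyte markers, and Saa3 and Chil3 both lead cluster 23, with 9 control and 54 primary cells, so neither ratio describes the whole class. S100a8 and S100a9, calcium-binding proteins of neutrophils, had ratios of 1576 (282 to 62312) and 616 (170 to 5097) over 1 and 2 control UMIs, with 99.2% of the primary UMIs in 5 cells.

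Lipid-associated macrophage genes had a median of 0.48 (percentile 100), with Lgals3 at 1.40-fold (1.31 to 1.5) and the fatty acid receptor Cd36 at a ratio of 0.389 (0.359 to 0.421), and glycolysis genes 0.42 (percentile 99.99), with Pkm at 1.35-fold. The inflammatory list had a median of 0.46 (percentile 99.99, 5 of 12 at least 1.5-fold higher and 4 lower), which fell to 0.15 with no filter on low counts and no longer stood apart. The alternatively activated list was lower (median -0.42, percentile 0.01), although Chil3 was higher and Retnla, another product of type 2 activation, had a ratio of 1.10 (1.09 to 1.12). That median was -0.14 with doublets kept, no longer apart. The alternatively activated list shares Mrc1, Cd163 and Cd209f with the perivascular resident list, so the lower medians of these lists are not independent results. Cluster 3, led by C1qa and Pf4, held 683 of 1009 control cells and 165 of 507 primary ones, cluster 6, led by Lyz2 and Lyz1, 178 and 202, and cluster 23, led by Saa3 and Chil3, 9 and 54. Filtering at 5% mitochondrial UMIs moved the log2 ratio of Ccl3 from -2.33 to -1.55. Weighting every cell alike moved that of Chil3 from 7.39 to 6.56, and at least 500 genes per cell moved that of S100a8 from 9.41 to 6.04.

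In dendritic cell-like cells, Hfe, a regulator of iron uptake, was 2.53-fold higher after primary infection (2.03 to 3.18), Itgae, the integrin CD103, 3.81-fold (1.86 to 8.58), the glycolysis gene Pfkp 2.51-fold (1.64 to 3.90) and the chromatin remodeller Chd7 2.35-fold (1.53 to 3.67). The chemokine gene Ccl9 was 4.12-fold lower (3.05 to 5.65) and Upb1 5.48-fold lower (2.94 to 11.1). Cluster 17, led by Cd209a, held 66 of 143 control and 41 of 123 primary cells. At resolution 0.5 it joined the macrophage class, and the log2 ratio of Ccl9 moved from -2.02 to -0.83. Clec4b1, a lectin gene 5.76-fold lower (2.81 to 13.3), then reversed to 0.26.

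The comparison of secondary infection with control asks what the fat holds after a repeated encounter. T cell-like cells were 3.31-fold (2.83 to 3.88) more frequent among all cells, NK cell-like cells 2.45-fold (1.72 to 3.50) and plasma cell-like cells 37.5-fold (13.9 to 142), from 4 of 4394 to 63 of 1847. Macrophage-like cells were 4.24-fold less frequent (3.45 to 5.26). B cell-like, ILC2-like, dendritic cell-like and endothelial cell-like cells had ratios of 0.925 (0.651 to 1.30), 0.835 (0.567 to 1.21), 1.06 (0.780 to 1.44) and 1.32 (0.914 to 1.90), not detectable at this depth. Resolution 0.5 gave 7.31% macrophage-like cells in the secondary library instead of 5.41%, and 1.57% dendritic cell-like cells instead of 3.47%.

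T cell-like cells of the secondary library again had higher type 2 genes, 12 of 13 at least 1.5-fold (median 3.39, or 3.02 with 3 members at their bound, percentile 100). Areg was 24.8-fold higher (15.4 to 42.8), Il1rl1 11.9-fold (7.20 to 21.0), Plac8 10.7-fold (7.69 to 15.2) and Gata3 5.61-fold (4.13 to 7.80), while Ccr4, again named after its values were seen, had a ratio of 0.587 (0.256 to 1.36). Il13 had 174 UMIs against 0, at least 31.6-fold higher (42.5% in 5 cells), Lgals7 was 58.0-fold (19.7 to 283) higher and Hdc 48.8-fold (13.3 to 406). Il13 UMIs were in 12.9% of these cells (9.47% thinned, no cell left out), against 0 of 273 control cells, where a floor of 3 cells allows a share of cells with a UMI of up to 1.10%. The background share of Il13 in fibroblast-like cells was 0.527%, at median depths of 2030.5 UMIs in T cell-like and 3350 in fibroblast-like cells. Cells with an Il1rl1 UMI were 42.1% against 1.83% in the control (27.4 and 1.83% thinned), with 0.632 and 0.503% in fibroblast-like cells. Of the 183 secondary T cell-like cells with a UMI of Il4, Il5, Il13 or Il1rl1, 180 (98.4%, 95.3 to 99.7) also had a CD3 UMI, against 30.0% of ILC2-like and 2.11% of fibroblast-like cells. The CD3 genes are also among the T cell markers used for naming, so this share is not independent of how the class was formed. Cluster 8 held 228 of 380 secondary cells.

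**Figure D2:**
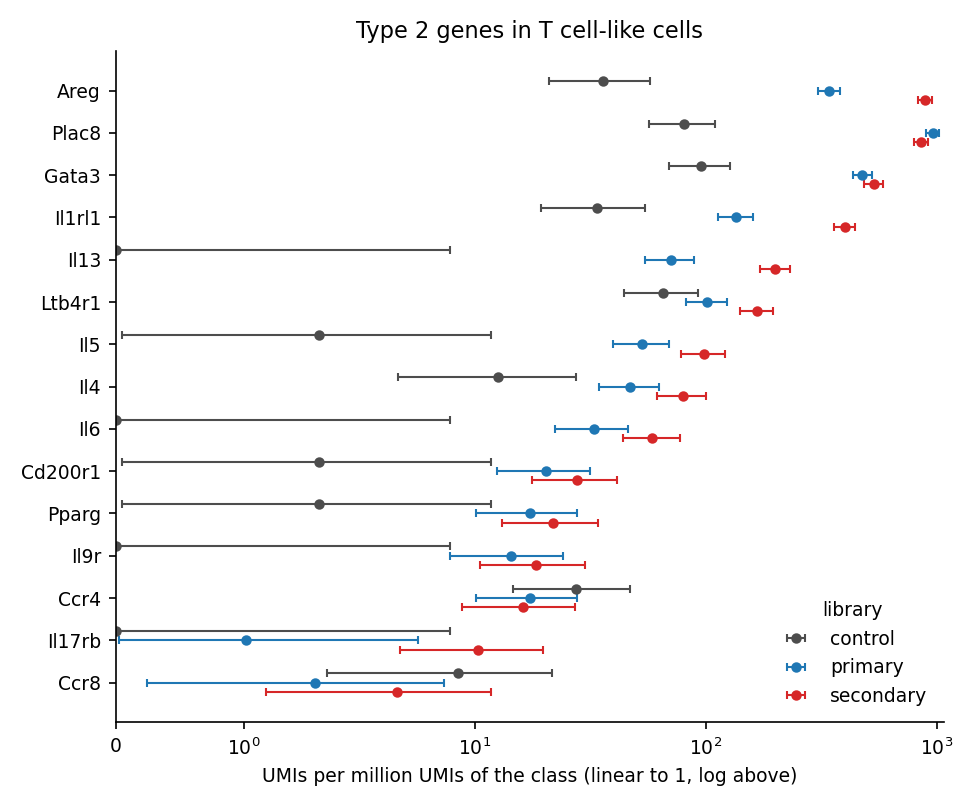
Level of each type 2 gene in T cell-like cells of the control, primary and secondary libraries (CPM in the class, linear to 1 and logarithmic above), with exact Poisson 95% intervals; 1 mouse per group. Areg lies at 35.8, 340 and 888 in the control, primary and secondary library.

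Type 1, type 17, naive and interferon response genes were lower in these T cell-like cells. Of 14 type 1 and cytotoxic genes, 10 were at least 1.5-fold lower (median -1.04, percentile 0), with the monocyte and memory T cell marker Ly6c2 at a ratio of 0.417 (0.342 to 0.508), the CD8 chain Cd8b1 at 0.497 (0.364 to 0.678) and the chemokine Ccl5 at 0.725 (0.682 to 0.770). Type 17 genes had a median of -2.68 (percentile 0, 3 of 5 lower). Cd163l1, a receptor of gamma-delta T cells, was 31.2-fold lower (7.99 to 268, from 34 UMIs to 2), Tmem176a 7.77-fold lower (5.32 to 11.6), and Blk, with 30 control UMIs and 0 secondary ones, at least 18.3-fold lower. Naive genes had a median of -0.81 (percentile 0), with Ccr7, the homing receptor for lymph nodes, in 2.89% of cells against 12.8% (2.11 and 7.33% thinned; background 0.105 and 0.126%). Interferon response genes were lower (median -0.56, percentile 0.03, 10 of 20). Regulatory genes (median 0.55, percentile 99.7), STAT6 targets (median 0.85, percentile 100) and immediate early genes (median 0.39, percentile 99.99, 10 of 22) were higher. Foxp3 UMIs were in 1.10% of control and 2.11% of secondary cells, with overlapping intervals, and Il10 UMIs in 0.366 and 0.263%. The regulatory list therefore does not show more regulatory T cells. The STAT6 median was 0.05 with no filter on low counts, and Lgals7 went from a log2 ratio of 5.56 to 4.93 when every cell weighed the same. Residency genes stood just apart (median 0.20, percentile 97.9), with 5 of 15 higher and 5 lower, but not when every cell weighed the same (0.09).

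Fibroblast-like cells of the secondary library had Mrgprg at 177 CPM, 209-fold higher (95.5 to 572) than in the control. Serpina3g, a protease inhibitor (chromosome 12, 104236245 to 104241939), was 52.3-fold higher (26.0 to 123), Col6a5, a chain of collagen VI (chromosome 9, 105856078 to 105960643), 19.7-fold (16.2 to 24.1) and Daglb 11.4-fold (9.85 to 13.2). Mrgprg, Serpina3g, Col6a5 and Daglb are all leading genes of subcluster 3, with 0 control cells and 50.1% of the secondary class. Their ratios therefore do not describe the whole class. Ackr4, which scavenges chemokines that guide cells to lymph nodes, was 4.06-fold lower (2.94 to 5.73), Krtdap 4.09-fold lower (3.19 to 5.32) and the LIM protein gene Crip2 3.26-fold lower (2.94 to 3.62). Krtdap is a leading gene of subcluster 1, which went from 16.0% of the control to 3.69% of the secondary class. Complement genes were higher (median 0.51, percentile 100, 5 of 11), with C4b at 6.40-fold (5.66 to 7.24) and C3 at 3.11-fold (3.03 to 3.19). STAT6 targets were also higher (median 0.37, percentile 99.98), with the eosinophil chemokine Ccl11 at 1.42-fold (1.37 to 1.48), while the monocyte chemokine Ccl2 had a ratio of 0.456 (0.413 to 0.502). Collagen and matrix genes split, with 6 of 29 at least 1.5-fold higher and 2 lower (median 0.09, percentile 98.0). Col3a1 was 1.79-fold higher (1.75 to 1.83), Fn1 1.64-fold (1.59 to 1.68), and Dcn had a ratio of 0.690 (0.675 to 0.704). That list did not stand apart when every cell weighed the same (0.03).

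Interferon response genes were lower in these cells, 15 of 34 at least 1.5-fold (median -0.50, percentile 0), with Ly6e at a ratio of 0.645 (0.601 to 0.691). Subcluster 7, led by the interferon-induced genes Ifit3, Rsad2 and Isg15, held 28 control cells and 2 secondary ones. MHC class II genes had a median of -1.50 (percentile 0; -1.30 without subcluster 6, which held 66 control cells and 1 secondary cell). Retnla UMIs were in 27.3% of control and 8.96% of secondary fibroblast-like cells (9.43 and 2.53% thinned, leaving out 0 cells), so this difference is not separated from free macrophage RNA either. Basement membrane genes had a median of -0.44 (percentile 0.58), with Lamc1 at 0.644 (0.598 to 0.693). TGF-beta response (median -0.12), adipogenic (-0.12), progenitor (-0.32, percentile 7.89) and stromal cytokine genes (-0.04) did not stand apart. Cluster 4 held 432 of 949 secondary fibroblast-like cells, against 2 of 2387 in the control, where cluster 0 held the largest part, 1152. With doublets kept, the log2 ratio of Serpina3g moved from 5.49 to 4.55.

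Macrophage-like cells of the secondary library, 100 cells, differed most in resident genes: 13 of 15 perivascular resident genes were at least 1.5-fold lower (median -3.24, or -2.33 with 2 members at their bound, percentile 0). Cd209f (chromosome 8, 4102787 to 4105835) was 50-fold lower (17.1 to 242) with 3 UMIs left, Folr2 15.9-fold lower (10.3 to 26.0), Pf4 15.5-fold lower (12.6 to 19.2) and F13a1, a clotting factor, 3.52-fold lower (2.77 to 4.54), while Mrc1, the mannose receptor, had a ratio of 0.856 (0.694 to 1.04). Ccl8 was again higher, 2.58-fold (2.06 to 3.20). Fxyd2, a subunit of the sodium pump, was 18.1-fold lower (9.81 to 37.8). Lyve1, a hyaluronan receptor of vessel-associated macrophages (ENSMUSG00000030787; chromosome 7, 110850607 to 110863239), had UMIs in 7% of cells against 57.7% in the control (5.05 and 36.9% thinned, with 1 and 0 cells left out), and in 0.211 and 0.545% of fibroblast-like cells. Median depths were 2970.5 and 2312 UMIs in macrophage-like and 3350 and 2857 in fibroblast-like cells.

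**Figure D3:**
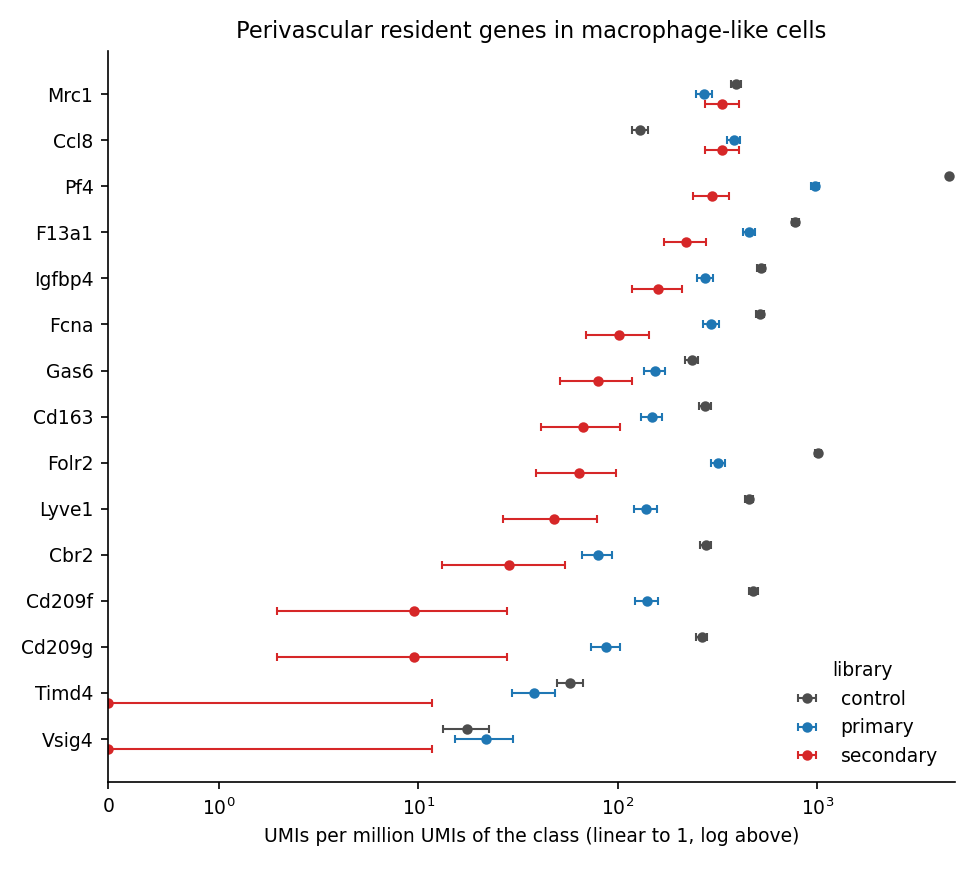
Level of each perivascular resident gene in macrophage-like cells of the control, primary and secondary libraries (CPM in the class, linear to 1 and logarithmic above), with exact Poisson 95% intervals; 1 mouse per group. Folr2 lies at 1011, 318 and 63.6, and Ccl8 is the member with its lowest level in the control.

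The genes of highest rank in these cells each had UMIs in a part of the class. Arg1, which turns arginine into ornithine (ENSMUSG00000019987; chromosome 10, 24915221 to 24927484), was 140-fold higher (77.8 to 276; 59.3% of UMIs in 5 cells), with UMIs in 26.0% of cells against 0.694% (17.2 and 0.496% thinned; 0.211 and 0.0419% of fibroblast-like cells). Chil3 was 343-fold higher (206 to 617), with 90.1% of its UMIs in 5 of 18 cells. Rnase2a, a ribonuclease of the eosinophil family, was 79.8-fold higher (36.2 to 208; 66.7% of UMIs in 5 cells) and the granule protease Prtn3 24.7-fold (14.0 to 45.5; 67.4% in 5 cells). Retnla had a ratio of 1.02 (0.993 to 1.06), and the alternatively activated list did not stand apart (median -0.22, percentile 6.83, 5 higher and 6 lower of 15), though it did at resolution 0.5 (-0.44). STAT6 targets had a median of 0.70 (percentile 99.98; 0.14 at no more than 5% mitochondrial UMIs, no longer apart) and glycolysis genes 0.69 (percentile 99.96, 10 of 16 higher), with Pkm at 1.92-fold (1.57 to 2.33). Lipid-associated genes had a median of 0.48 (percentile 99.3), with Lgals3 at 1.88-fold (1.68 to 2.11), and inflammatory genes -0.66 (percentile 0.49), with Ccl3 10.6-fold lower (6.18 to 20) but Il1b 2.07-fold higher (1.76 to 2.43). Neither list stood apart at resolution 0.5 (0.34 and -0.34). MHC class II genes were lower (median -0.48, percentile 1.85; -0.15 with doublets kept, no longer apart). Cluster 6 held 79 of 100 secondary cells and cluster 3 held 11, against 178 and 683 of 1009 in the control. At no more than 5% mitochondrial UMIs the log2 ratio of Cd209f moved from -5.56 to -6.90, that of Folr2 from -3.98 to -4.76 and that of Fxyd2 from -4.15 to -4.80. Weighting every cell alike moved Chil3 from 8.26 to 7.65 and Rnase2a from 5.99 to 6.61, and resolution 0.5 moved Prtn3 from 4.49 to 3.90.

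Dendritic cell-like cells of the secondary library numbered 64, of which cluster 17 held 35, against 66 of 143 in the control. Ifitm1, an interferon-induced membrane protein, was 11.6-fold higher (5.69 to 26.7; 85.5% of UMIs in 5 cells). Cd209e, a lectin gene with 0 control UMIs and 30 secondary ones (66.7% in 5 cells), was at least 19.0-fold higher, and Tmem238, with 0 and 20, at least 12.7-fold, and also higher in fibroblast-like (3.25-fold), macrophage-like (3.54-fold) and T cell-like cells (3.76-fold). Arl5c was 9.35-fold lower (3.49 to 35.2) and Pid1 4.49-fold lower (2.78 to 7.65). Taf10, a subunit of the general transcription machinery, was 7.20-fold higher (4.75 to 11.3), and was also higher in fibroblast-like (3.27-fold), macrophage-like (4.57-fold) and T cell-like cells (3.29-fold). Cxx1b, 8.35-fold lower (3.92 to 21.2), has near-identical copies beside it, so its count is uncertain. Interferon response (median -0.37, percentile 0.615) and MHC class II genes (median -0.29, percentile 1.41) were lower and glycolysis genes higher (median 0.51, percentile 99.8), but at resolution 0.5 the first pair did not stand apart (-0.13 and -0.18), and with balanced neighbours neither did glycolysis (0.41). With the same change to resolution 0.5, which moves cluster 17 to the macrophages, the log2 ratio of Cd209e was 0 in place of 5.48, that of Tmem238 3.17 in place of 4.91 and that of Pid1 -3.21 in place of -2.13. With doublets kept Ifitm1 moved from 3.36 to 2.36, and when every cell weighed the same Arl5c moved from -3.02 to -2.39.

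**Figure D4:**
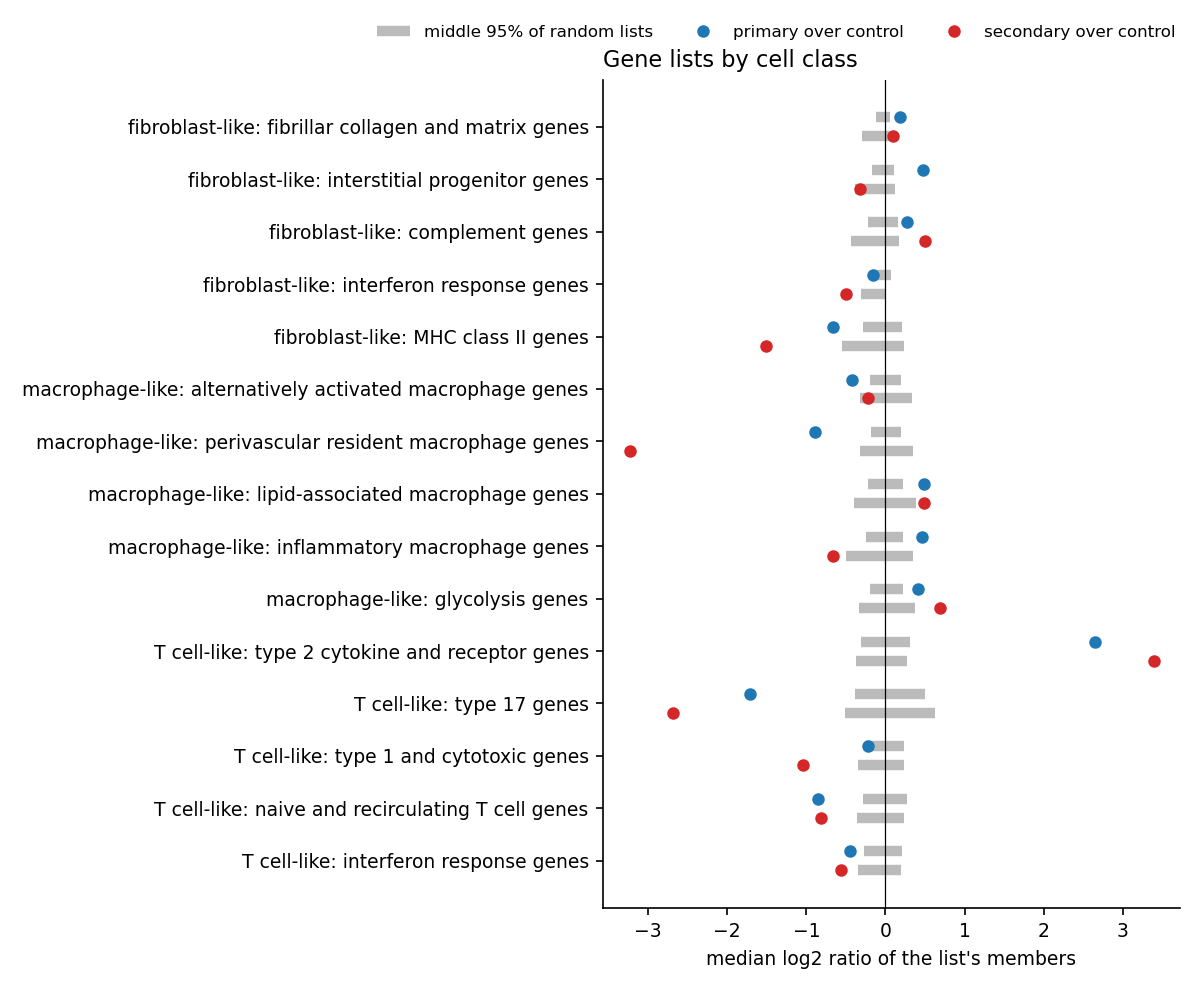
Median log2 ratio of a gene list's members for 15 pairs of list and class in fibroblast-like, macrophage-like and T cell-like cells. The interferon response list is drawn in both fibroblast-like and T cell-like cells. Points are primary or secondary over control, and grey bars the middle 95% of 10000 random lists matched on size and expression, with 1 mouse per group. Type 2 genes of T cell-like cells lie at 2.64 and 3.39, and perivascular resident genes of macrophage-like cells at -0.89 and -3.24.

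The comparison of secondary with primary infection asks how a repeated encounter differs from a first one, each taken 11 to 13 days after the last gavage. The secondary mouse alone had 1 mg of pyrantel and 4 to 5 weeks of recovery, which cannot be told apart from the repeated infection. T cell-like cells were 1.98-fold (1.72 to 2.27) more frequent in the secondary library and plasma cell-like cells 2.97-fold (2.02 to 4.38), while macrophage-like cells were 2.11-fold (1.70 to 2.64) and B cell-like cells 1.76-fold (1.28 to 2.45) less frequent. In T cell-like cells, type 2 genes were higher still, 8 of 14 at least 1.5-fold (median 0.73, percentile 100), with Il1rl1 at 2.97-fold (2.42 to 3.66) and Areg at 2.61-fold (2.29 to 2.97), while Gata3 had a ratio of 1.12 (0.980 to 1.27). Type 1 and cytotoxic genes were lower (median -0.57, percentile 0, 6 of 14), with Cd8b1 2.2-fold lower (1.69 to 2.88), as were type 17 genes (median -0.84, percentile 0.0900). Naive genes did not stand apart (median -0.17, percentile 16.6). Zrsr1, a splicing factor gene copied from Zrsr2 and so with an uncertain count, was 8.13-fold higher (5.24 to 13.2) and also higher in fibroblast-like (2.61-fold), macrophage-like (2.69-fold) and dendritic cell-like cells (1.71-fold), and Irs2, an adaptor of insulin and interleukin 4 receptors, 5.45-fold (2.89 to 11.1). Ccl3, 7.67-fold lower (4.10 to 15.9), had 93.7% of its primary UMIs in 5 cells, and its log2 ratio reversed from -2.84 to 0.40 at no more than 5% mitochondrial UMIs.

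In fibroblast-like cells, Cyp26b1 was 8.22-fold higher in the secondary than in the primary library (6.43 to 10.6) and Col6a5 6.15-fold (5.49 to 6.89), while Krtdap was 5.25-fold (4.11 to 6.79) and Igfbp5, which binds insulin-like growth factors, 4.30-fold lower (3.89 to 4.77). Col6a5 is a leading gene of subcluster 3, which held 7.01% of the primary and 50.1% of the secondary class. Krtdap, Igfbp5 and Pi16 are leading genes of subcluster 1, which held 30.3 and 3.69%. The ratios of genes that lead a subcluster are not separated from these changes in composition. Interstitial progenitor genes were lower, 8 of 12 at least 1.5-fold (median -0.92, percentile 0), with Pi16 2.31-fold lower (2.2 to 2.43) and the surface marker Cd34 at a ratio of 0.668 (0.629 to 0.710). Cells with a Pi16 UMI were 46.4% against 57.2% (28.2 and 41.4% thinned, with 0 and 16 cells left out), and 1.05 and 3.68% in T cell-like cells. Complement genes were higher (median 0.34, percentile 99.9), with C3 at 1.86-fold (1.82 to 1.90). Interferon response genes (median -0.42, percentile 0.01) and MHC class II genes (median -0.74, percentile 0.07) were lower, the latter not apart with no filter on low counts (-0.44) and beside fewer cells with a Retnla UMI, 8.96 against 20.1% (2.53 and 7.24% thinned). Adipogenic genes were lower (median -0.36, percentile 1.05), but not apart among members with at least 50 UMIs (-0.25), and collagen (median -0.08) and basement membrane genes (median -0.29) did not stand apart. Cluster 2, led by Igfbp5, Mfap5 and Pi16, held 625 of 2598 primary and 13 of 949 secondary cells, and cluster 4 held 356 and 432.

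Macrophage-like cells had lower perivascular resident genes in the secondary than in the primary library, 13 of 15 at least 1.5-fold (median -1.51, or -1.44 with members at their bound, percentile 0), with Cd209f 14.6-fold lower (4.95 to 71.5) and the chemokine gene Ccl12 7.94-fold lower (3.35 to 24.7; 49.8% of primary UMIs in 5 cells). Inflammatory genes were also lower (median -1.03, or -0.80 at the bound, percentile 0, 8 of 12), while Il1b was 1.60-fold higher (1.35 to 1.89). Ccl24, an eosinophil chemokine, was 3.53-fold higher (3.16 to 3.94; 40.9% of UMIs in 5 cells) and Plac8 3.32-fold (2.92 to 3.76; 47.8% in 5 cells). The subcluster with the monocyte genes Plac8 and Ly6c2 held 11.6% of the primary and 40.0% of the secondary class. The alternatively activated list was lower (median -0.31, percentile 0.24) and the lipid-associated list higher (median 0.31, percentile 99.3), but neither stood apart with doublets kept (-0.05 and 0.19). Cluster 6 held the largest part of the class in both libraries, 202 of 507 and 79 of 100. In dendritic cell-like cells, Ifitm1 was 20.8-fold higher (8.41 to 66.7; 85.5% of UMIs in 5 cells) and AA467197 4.08-fold (2.97 to 5.67; 59.2% in 5 cells), while Cxx1b was 5.88-fold lower (2.72 to 15.1) and Xcr1, the receptor of cross-presenting dendritic cells, 3.89-fold (2.06 to 8.10). Cluster 16 held 75 of 123 primary and 21 of 64 secondary dendritic cell-like cells. At no more than 5% mitochondrial UMIs Cd209f moved from a log2 ratio of -3.74 to -4.98. At resolution 0.5 AA467197 moved from 2.00 to 1.27 and Ifitm1 from 4.06 to 3.33.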

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

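Each of these results was singled out after its values were seen, because a list moved in opposite directions in different classes or infections, or because RNA of other cell types or tissues, which the comparisons do not cover, exceeded the control. None of these differences was tested.

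MHC class II genes, which present antigen to helper T cells, had a median log2 ratio of primary infection over control of -0.67 in fibroblast-like cells and 0.88 in T cell-like cells. The first lies beside less macrophage RNA in the same droplets, and the second rests on 5 measured genes and turned to -0.15 with at least 500 genes per cell and to -0.82 with at most 5% mitochondrial UMIs. Immediate early and dissociation genes, which respond to activation and to tissue digestion, had a median ratio of secondary infection over control of -0.31 in macrophage-like and 0.39 in T cell-like cells. Over primary infection the medians were -0.31 in macrophage-like, 0.40 in T cell-like and -0.19 in dendritic cell-like cells. Inflammatory macrophage genes had a median of 0.46 in primary and -0.66 in secondary infection over control.

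Pancreatic acinar genes, which code for digestive enzymes, stood at 29.1 CPM over all cells of the primary library, against 6.42 in the control and 5.12 in the secondary library. A single fibroblast-like cell held 299 of the 313 acinar UMIs of its class, so the excess is that of 1 droplet. S100a8 and S100a9 together stood at 137 CPM over all cells of the primary and 336 CPM of the secondary library, against 0.604 in the control. In the primary library 9 cells with at least 10 of these UMIs held 1850 of 1893, and in the secondary library 8 cells held 2059 of 2099. The macrophage class held 1470 of the primary and 1999 of the secondary UMIs.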

How the results depend on the processing

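Of the tests here, 3 alternatives were added after the data had been seen: droplets with fibroblast and ILC2 genes counted as fibroblasts, macrophages without cells high in S100a8 and S100a9, and fibroblasts without subcluster 6. No paired analysis was possible because each group is 1 mouse. Of the 336 shares of cells recomputed under the other alternatives, 309 stayed inside the interval of the reported share. Of 2042 medians of lists, 1899 kept their direction and their call, and 6 reversed. Of 720 ratios of named genes, 681 stayed inside their interval, and 4 reversed. Of 81 shares of cells with a UMI, 20 stayed inside their interval after thinning, which lowers such shares by construction, and 0 reversed. Under the added alternatives the same held for 5 of 6 shares, 135 of 138 medians and 16 of 18 ratios, with 0 reversals.

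Clustering settings moved cells with Cd209a, cluster 17, from dendritic cell-like to macrophage-like. At resolution 0.5 dendritic cell-like cells were 1.75, 1.85 and 1.57% of control, primary and secondary cells, macrophage-like cells 24.5% of control and 7.31% of secondary cells, and 62.0, 34.2 and 17.7% of immune cells. With balanced neighbours dendritic cell-like cells were 1.82, 1.80 and 1.52%, and macrophage-like cells 24.5, 12.5 and 7.36% of all and 61.9, 34.2 and 17.8% of immune cells. With doublets kept dendritic cell-like cells were 2.04, 2.08 and 1.81%, while in the secondary library fibroblast-like cells were 53.8%, non-immune classes 56.9% and macrophage-like cells 7.20%. Macrophage-like cells were then 61.7% of control and 17.5% of secondary immune cells. At least 500 genes per cell gave 2.21% and 3.83% B cell-like cells in the control and primary library. Counting the mixed droplets as fibroblasts, which adds them by construction, gave 55.9% in the control.

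In macrophage-like cells the alternatively activated list lost its call in primary over control at resolution 0.5 (-0.16), with balanced neighbours (-0.17) and with doublets kept (-0.14), and gained one in secondary over control (-0.44, -0.48 and -0.41). In secondary over control the calls of the inflammatory list ended at the same settings (-0.34, -0.44 and -0.34) and when every cell weighed the same (-0.49). Those of the lipid-associated list ended at these 4 settings (0.34, 0.27, 0.26 and 0.30) and with at least 500 genes (0.32). The inflammatory list in primary over control lost its call without a filter on low counts (0.15) and with at least 50 UMIs (0.15). The cause was not tested.

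In dendritic cell-like cells, primary over control, Clec4b1 reversed from -2.40 to 0.26 at resolution 0.5 and to 0.16 with doublets kept, and interferon response genes from -0.41 to 0.0407 and 0.19. In secondary over primary, interferon response genes reversed to 0.25 with at least 50 UMIs. The cause was not tested.

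In T cell-like cells the regulatory list in primary over control reversed to -0.30 with at least 50 UMIs and lost its call when every cell weighed the same (0.26), and type 1 genes gained one with at least 500 genes (-0.37). MHC class II genes in primary over control reversed to -0.15 with at least 500 genes and to -0.82 with at most 5% mitochondrial UMIs. Residency genes in secondary over control lost their call with at least 500 genes (0.11), at most 5% mitochondrial UMIs (0.16), no filter on cells (0.19), no filter on low counts (0.0893) and every cell weighing the same (0.0930). Ccl3 in secondary over primary reversed from -2.84 to 0.40 with at most 5% mitochondrial UMIs and to 0.0848 when thinned to the shallowest library, and 5 cells held 93.7% of its UMIs. The cause was not tested.

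In fibroblast-like cells the collagen list in secondary over control lost its call with doublets kept (0.0630), thinned to the shallowest library (0.0807), with every cell weighing the same (0.0270), with at least 50 UMIs (0.0900) and with mixed droplets counted as fibroblasts (0.0738). The adipogenic list in primary over control lost its call with doublets kept (0.11) and every cell weighing the same (0.11). In B cell-like cells the activation list gained a call in primary over control with at least 50 UMIs (-0.32), and in secondary over control with at most 5% mitochondrial UMIs (-0.35), no filter on cells (-0.44) and a prior of 5 UMIs (-0.30). The cause was not tested.

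The directions of the macrophage, T cell, NK cell and plasma cell shares, of the type 2 list in T cell-like cells and of the perivascular resident list in macrophage-like cells held under every alternative run. Of the 4 classes whose genes were named, the secondary macrophage and dendritic cell classes have the fewest cells, 100 and 64, which widens their intervals.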

Other observations

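Of the tests in this part, those of random joining over all droplets and of other myeloid cells inside the macrophage class were set before their results were seen, and the others were chosen after. Helper and killer T cells can be told apart by Cd4 and Cd8a. Among T cell-like cells, 9.89, 16.2 and 21.1% of the control, primary and secondary cells had a Cd4 UMI (4.40, 8.55 and 10.0% thinned), and 10.3, 8.01 and 5.00% a Cd8a UMI (5.49, 5.48 and 4.21% thinned). Type 2 cytokine genes other than Il13 followed the order of the libraries, with Il5, the growth factor of eosinophils, in 0.366, 6.06 and 8.68% of cells (0.366, 2.63 and 5.00% thinned). Il4, which drives class switching in B cells, was in 2.2, 7.58 and 11.6% (0.366, 2.63 and 4.74% thinned). Of the STAT6 targets, Cish was 3.23-fold (2.08 to 5.2) and Socs2 2.33-fold (1.69 to 3.28) higher in the secondary library than in the control. Foxp3, the factor of regulatory T cells, had UMIs in 1.10, 0.866 and 2.11% of cells, with intervals that overlap in all 3 libraries. Thinning left out 0, 6 and 0 cells, and UMIs of these 5 genes were in at most 0.154% of the fibroblast-like cells of any library.

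Dendritic cell-like cells carried 3, 35 and 149 UMIs of the eosinophil chemokine Ccl24 in the control, primary and secondary library. Its level was 11.7-fold (3.69 to 59.5) higher after primary and 94.3-fold (31.7 to 463) higher after secondary infection. Ccl24 is a leading gene of macrophage cluster 6 and stood at 866, 483 and 1705 CPM in macrophage-like cells of the same libraries. Cluster 17 held 35 of the 64 secondary dendritic cell-like cells and joined the macrophages at a lower clustering resolution. The ratios are therefore not separated from macrophage-like cells placed in this class or from free macrophage RNA. The activation list of B cell-like cells did not stand apart at the main settings, with medians of -0.17 in primary over control, -0.33 in secondary over control and -0.08 in secondary over primary, but it was lower than random lists under some alternatives, with -0.32 in primary over control among members with at least 50 UMIs. Cell cycle and oxidative phosphorylation genes did not stand apart in any of the 4 classes and 3 comparisons. Intestinal epithelial and platelet genes had fewer than 4 measured members in each class. Adipocyte RNA was lower in macrophage-like cells after primary (median -1.49, percentile 0.015) and secondary infection (median -2.61, or -1.43 with members at their bound). Red blood cell RNA was higher in primary than in control macrophage-like cells (median 5.28, percentile 100), where 1 cell held 171 of 218 globin UMIs, and fibroblast-like cells (median 1.73). Acinar genes of fibroblast-like cells had a median of 4.21 in primary over control, or 3.26 at the bound. Immediate early genes of fibroblast-like cells had a median of -0.20 in primary over control (percentile 0.05).

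The unnamed cluster with fibroblast and ILC2 genes held 70, 50 and 41 droplets. Random pairing at the assumed doublet rate of 0.8% per 1000 barcodes gives 4.58, 5.2 and 0.661. That rate was not measured here, so these counts do not give the size of the excess. Droplets with fibroblast genes per 100 single cells were 71.4 for ILC2-like, 13.5 for T cell-like, 11.1 for B cell-like, 12.2 for NK cell-like and 8.93 for macrophage-like partners. Pairs with fibroblast genes were 5.28-fold (4.21 to 6.65) more frequent per ILC2-like cell than per T cell-like cell, and 4.20-fold (3.24 to 5.42) with CD3-bearing droplets set aside, which argues against random joining of cells. Free RNA would fall on all fibroblast droplets of a library by depth, which gives 0.0372 droplets with at least 5 UMIs of ILC2 markers. Of 6095 droplets of the fibroblast class and the unnamed cluster together, 60 (45.8 to 77.2) held that many, 59 of them in the unnamed cluster. This argues against free RNA spread by depth. A single cell type that uses both sets of genes cannot be told apart from pairs, since the median depth was 0.940 of the sum of the medians of both classes, which either allows. ILC2 attached to fibroblasts that the digestion did not separate may account for the droplets, a hypothesis with no direct test here.

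Lower resident macrophage genes after secondary infection came from cells no shallower than the control ones, with medians of 2970.5 and 2312 UMIs. A poor release in the digestion that macrophages share with endothelial cells is argued against by the endothelial share, whose ratio of 1.32 (0.914 to 1.90) lies above the macrophage upper bound of 0.290, but one of macrophages alone, or shared with mesothelial cells (ratio 0.487, 0.209 to 1.01), stays open. Cells with UMIs of at least 2 C1q genes went from 88.9 to 53.0% of the class and a subcluster with monocyte genes (Plac8, Ly6c2) from 2.28 to 40.0%. Other myeloid cells may therefore account for a part or all of the difference. Among the C1q cells the median was -2.57, against -3.24 in the class. This cannot exclude other myeloid cells as the whole cause. Clusters 3, 13 and 23 held 11, 5 and 5 secondary cells, so most of the 53 secondary C1q cells came from cluster 6, which is close to monocytes. A loss of resident macrophages, or of their program, with repeated infection may be held as a hypothesis, but with 1 mouse per group infection and any other difference between the mice cannot be told apart.

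Ribosomal protein pseudogenes, near-identical copies of expressed genes, were higher in the secondary than in the primary library in each of the 4 classes, with a lowest median log2 ratio of 0.81 and all 15 copies higher in fibroblast-like cells. Their parent genes had a highest median of 0.14, which argues against more ribosomal protein RNA. A like shift over primary in every class fits reads of a parent counted for its copy, which may differ between libraries for technical reasons that were not tested. Secondary over control was less alike, with medians of the copies of 0.62, 0.72, 0.29 and 0.44 in fibroblast-like, macrophage-like, T cell-like and dendritic cell-like cells. In primary over control the medians of the copies were lower in all 4 classes, from -0.24 to -0.50. Infection as the reason for the shift was not tested.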
